A study of Arabidopsis thaliana with 11 samples.

How the data were processed

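Guard-cell-enriched samples of Arabidopsis thaliana Col-0 were profiled on 1-colour Agilent arrays, with 100 ng of RNA labelled with Cy3 per sample, per the labels' protocols. Plants entered the experiment at 4 to 5 weeks of age and grew with 12 h of light at 22 °C by day and 16 °C by night. The groups were no salt (4 samples), 1x salt (3 samples) and 3x salt (4 samples), taken from the labels. The extract protocol speaks of 4 samples per treatment, and the 3 1x salt samples present here were used.

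The scanner files came from Agilent Feature Extraction 11.5.1.1, per the file headers. They hold a processed signal per spot, in intensity units, that was background-subtracted and detrended, with small values replaced by the spot's error estimate, per the file headers. They also hold the raw median intensity of each spot and of its local background, per the file headers. The arrays lay on 6 slides and were scanned on 1 day. Slide 1 held no-salt 1, 1x salt 1 and 3x salt 1, slide 2 held no-salt 2 and 1x salt 2, slide 3 held 3x salt 2, slide 4 held no-salt 3 and 1x salt 3, slide 5 held 3x salt 3, and slide 6 held no-salt 4 and 3x salt 4. A table of normalised values per locus, deposited by the authors, is on a log2 scale as judged by comparison with the scanner values. Its background correction and normalisation are not given in the sources used here, and its centring stays unknown. Its column medians were 8.29 to 8.34, it lists 28718 loci (19186 of them among the genes tested), and deviations of each array from the gene means correlated across genes with its own column at 0.79 to 0.93, against 0.23 to 0.85 for the other column that came closest.

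Of 43603 probes, 34348 were matched to 25410 loci by locus name or by RefSeq name without version, through a gene table of assembly TAIR10.1, while the file headers name annotation build TAIR 10. The other 9255 probes, 1247 of them with RefSeq names, kept the name in the files. No coordinates are given. The processed signal was taken as log2 minus each array's 75th percentile over non-control spots, outlier spots were left out, and repeat spots were averaged (50 probes). The brightest probe stood for a gene (6946 loci have several), and genes well above background on at least 3 of the 11 arrays were kept, 23458 of 34290, of which 219 lacked a value on an array. The number of arrays limits the precision.

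One linear model over all 11 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom, with package data.table at version 1.17.8), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Every adjusted p of a gene comes from limma. For a gene not well above background on any array of a group, a fold is given as "at least". It sets the mean of the brighter group against the mean of, per array of the dim group, the higher of the lowest signal among probes well above background and the probe's own signal. The 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons. No call of a list holds with an estimated correlation. fry, run as an alternative, tests whether a list's own genes move on balance one way, or in either direction, without comparing them with other genes. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and python 3.11.15.

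The lists cover ABA-responsive genes, ABA receptors, clade A PP2C phosphatases, ABA kinases and ABF factors, ABA synthesis and breakdown, guard cell ion channels and pumps, sodium, potassium and chloride homeostasis, compatible solute synthesis, proline breakdown, photosynthesis, wax and cutin, antioxidant genes, jasmonate, salicylate, heat shock, senescence, guard cell identity and light signalling, vascular markers, pavement cell and trichome markers, aquaporins, expansins and xyloglucan transglucosylases, clock genes, and touch and wound rapid-response genes. The lists, the groups, the tests and the rule for named genes were chosen before the data were examined. That rule takes, per comparison, the 6 largest rises and 6 largest falls with a locus, an adjusted p below 0.05 and no overlap between the arrays. It adds the list members with the smallest adjusted p, up to 4 where the list passed and up to 2 otherwise, and always SLAC1, GORK, KAT1, HKT1, NHX1, SOS1, NCED3, P5CS1 and RD29B.

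The fit was tested on simulated data for 23458 genes with 200 changed. For 1x salt against no salt it recovered 68% of changes of 1 and 20% of changes of 0.5 on the log2 scale, with 3 unchanged genes called. For 3x salt against no salt it recovered 74% and 29%, with 4 unchanged genes called. In both, 10 of 10 shifted lists and 0 of 10 unshifted lists passed, and 0 changed genes were called in the wrong direction by limma. The simulated noise was independent between genes and between arrays, unlike that of the real lists and close arrays. The simulation therefore does not show how often unshifted lists or unchanged genes would pass in these data. Alternatives were normexp background correction (offset 50, planned on the mean spot intensity and run on the median spot and background intensities), quantile normalisation, no filter or a filter on all 11 arrays, the mean of a gene's probes, the authors' table, the replicate number or slide as a block, only the 2 groups compared, trend and robust moderation, array weights, a fold of at least 2, camera with an estimated correlation, fry, and leaving out each array. Median centring and close arrays averaged or as a random block were chosen after the data were seen. Splits of the arrays of 2 groups (35 per comparison) were refitted in full.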

Results

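Gene expression was measured in guard-cell-enriched samples of Arabidopsis thaliana (Col-0) kept under 2 salt regimes or tap water. Guard cells are the epidermal cells that open and close the stomatal pore. Each treatment day, pots stood in the solution for 2 h. Plants of the 3x salt group received 75 mM NaCl on days 1 and 2, 150 mM on days 7 and 8, and 200 mM on days 13 and 14. Plants of the 1x salt group received only the last of these rounds, and the no-salt group received tap water. All groups were harvested on day 15, after 4 h of light. The 4 no-salt, 3 1x salt and 4 3x salt samples each had their own 1-colour Agilent array.

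Each array carried 43803 non-control spots, of which 66.24% to 80.25% were well above background. The 75th percentile of the processed signal lay between 1342 and 2853 intensity units, and at most 2 spots were saturated on an array. The array of 1x salt sample 3 had the highest share of spots above background (80.25%) and 442 outlier spots, against 9 to 38 on the other arrays. After collapse to the brightest probe of each gene and removal of dim genes, 23458 genes were tested, 19321 of them with a locus name. The median standard error of a log2 difference was 0.132 for 1x salt against no salt, 0.122 for 3x salt against no salt and 0.132 for 3x against 1x salt.

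The first principal component held 51.2% of the variance and separated 3x salt (scores 63.3 to 70.2) from no salt (-56.5 to -51.3). The 1x salt arrays lay between or near no salt on it, with array 1 at -46.2 and arrays 2 and 3 at -2.6 and 1.4. The second component (18.8%) set the 1x salt arrays (43.1 to 53) apart from no salt (-30.1 to -22.4), and it split 3x salt arrays 1 and 2 (7.7 and 9.7) from arrays 3 and 4 (-32.2 and -29.7). Several arrays of a group lay close to each other. The SD of their log2 differences was 0.122 to 0.14 among no-salt arrays 2, 3 and 4, 0.157 between 3x salt arrays 1 and 2, and 0.156 between 3x salt arrays 3 and 4. 1x salt array 1 differed from arrays 2 and 3 by 0.433 and 0.448, and these differed from each other by 0.193. The labels do not say whether the samples of a group came from separate plants or preparations. The p-values therefore measure only the spread between these samples, which may be technical, and each count of genes is also given with close arrays averaged to 1 sample, a setting chosen after the data were seen.

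**Figure D1:**
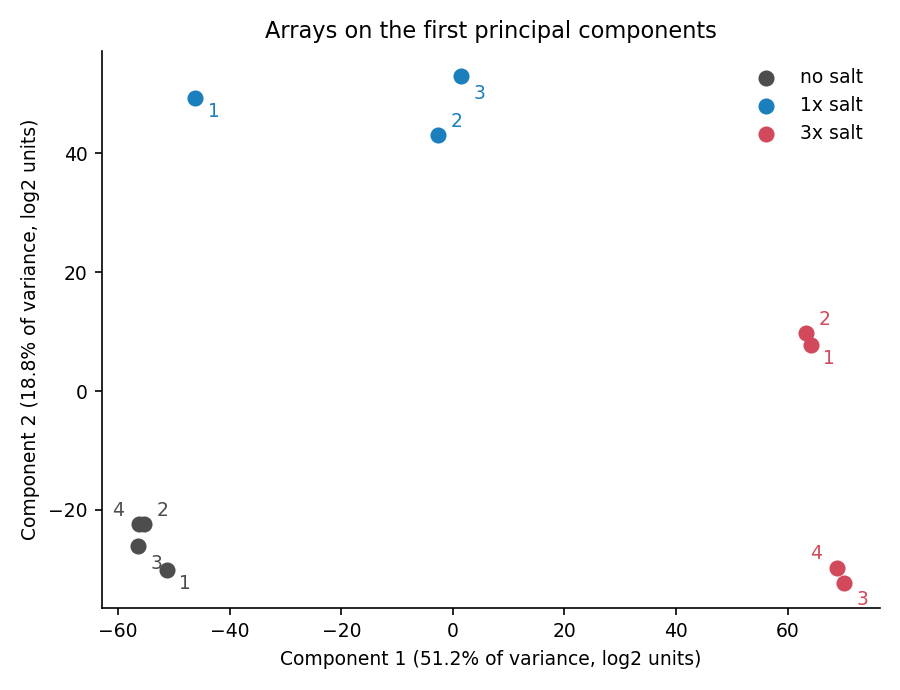
Scores of the 11 arrays on the first 2 principal components of 23239 genes (x axis, component 1; y axis, component 2, both in log2 units), coloured by group and numbered by replicate. 3x salt arrays lie at 63.3 to 70.2 on component 1 and no-salt arrays at -56.5 to -51.3, and 1x salt array 1 lies at -46.2, apart from 1x salt arrays 2 and 3.

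The comparison of 1x salt with no salt asked which genes respond to salt given only on the last treatment days. Of 14 touch and wound rapid-response genes, which include the cold-response factors CBF1, CBF2 and CBF3 and the defence regulator WRKY40, 10 fell, and of 12 salicylate genes, which include immune regulators and pathogenesis-related proteins, 8 fell. Of 17 aquaporins, which are membrane water channels, 7 rose, as did 6 of 21 wax and cutin genes and 10 of 13 vascular markers. These lists passed camera at a preset correlation, with adjusted p from 0.317 to 0.452 with an estimated correlation. CBF1 (AT4G25490) fell by 2.47 on the log2 scale (SE 0.10, limma adjusted p = 2.62e-06) and the tonoplast aquaporin TIP2;1 (AT3G16240) rose by 2.60 (SE 0.23, adjusted p = 0.000212).

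Among the largest rises in 1x salt were CWINV5 (AT3G13784), of the cell wall invertase family, the xyloglucan transglucosylase XTH33 (AT1G10550) and 2 members of the glutaredoxin family. CWINV5 was not well above background in no salt and was at least 35.7-fold higher in 1x salt (adjusted p = 0.00119). XTH33 rose by 4.89 (SE 0.79, adjusted p = 0.00348). The glutaredoxins AT3G21460 and AT4G15660 rose by 4.73 (SE 0.38, adjusted p = 0.000151) and 4.70 (SE 0.61, adjusted p = 0.00131). AT4G36850 rose by 4.96 (SE 0.22, adjusted p = 3.36e-06) and AT5G05965 by 4.71 (SE 0.61, adjusted p = 0.00129). AT5G05965 and AT4G15660 were above background on 1 of the 4 no-salt arrays. Among the largest falls, ARD3 (AT2G26400), an acireductone dioxygenase of methionine salvage, fell by 5.61 (SE 0.61, adjusted p = 0.00055), and FMO1 (AT1G19250), needed for systemic acquired resistance, fell by 4.57 (SE 0.26, adjusted p = 1.69e-05). UMAMIT19 (AT1G21890) fell by 4.27 (SE 0.73, adjusted p = 0.00463). ARD3 and UMAMIT19 were above background on 1 of the 3 1x salt arrays and FMO1 on 2. NAS1 (AT5G04950), a nicotianamine synthase, ERF14 (AT1G04370) and SEP1 (AT5G15800), a floral MADS-box factor, were not well above background in 1x salt. They were at least 17.5-fold (adjusted p = 0.000315), 8.79-fold (adjusted p = 0.000908) and 9.05-fold lower (adjusted p = 0.0015).

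Of 14 touch and wound genes, 10 fell and none rose, and 13 fell adjusted over the list alone (median log2 difference -1.73, camera adjusted p = 5.04e-11, adjusted p = 0.352 with an estimated correlation). Besides CBF1, CBF2 (AT4G25470), CBF3 (AT4G25480) and WRKY40 (AT1G80840) fell by 2.16, 1.95 and 2.42 (adjusted p = 0.000672, 0.000937 and 0.0015). On slides 1, 2 and 4, the slides that hold both groups, the median was -0.72, -2.17 and -2.29, and it was -1.69 with slide as a block (adjusted p = 8.17e-09). No test here separates salt from sample handling for touch, wound and jasmonate genes. Of 12 salicylate genes, 8 fell by either adjustment and none rose (median -1.0, camera adjusted p = 3.37e-07, adjusted p = 0.317 with an estimated correlation). They included PAD4 (AT3G52430), a regulator of basal resistance, which fell by 2.1 (SE 0.21, adjusted p = 0.000372), CBP60G (AT5G26920), a calmodulin-binding activator of salicylate synthesis, by 1.89 (adjusted p = 0.00293), PBS3 (AT5G13320) by 1.11 (adjusted p = 0.00167) and PR5 (AT1G75040) by 1.28 (adjusted p = 0.00379). The medians on slides 1, 2 and 4 were -0.58, -1.14 and -1.19, and -1.0 with the slide block (adjusted p = 3.29e-06). Of 20 jasmonate genes, 4 fell and 8 fell adjusted over the list alone (median -0.46, camera adjusted p = 0.00685, adjusted p = 0.513 with an estimated correlation and 0.0732 with fry). The mean level of the list against no salt was -0.42 on no-salt array 1, 0.12 to 0.18 on the other no-salt arrays, and -0.43 on 1x salt array 2, without which the median was -0.80. The repressors JAZ8 (AT1G30135), JAZ5 (AT1G17380) and JAZ1 (AT1G19180) fell by 1.12, 1.2 and 0.99, and AOS (AT5G42650), allene oxide synthase, fell by 0.68 (adjusted p = 0.0262, 0.0273, 0.0375 and 0.0476). The jasmonate medians were 0.01, -0.49 and -0.64 on slides 1, 2 and 4 and -0.42 with the slide block (adjusted p = 0.0294). Each of these 4 single-gene calls was lost when no-salt array 2, 3 or 4 or 1x salt array 3 was left out (adjusted p from 0.0669 to 0.121), and with the slide block (0.0522 to 0.175). The 3 JAZ calls were also lost without 1x salt array 2 (0.0786 to 0.106), and the AOS call without 1x salt array 1 (0.114) or 3x salt array 1, 2 or 3 (0.0512 to 0.0589).

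Of 17 aquaporins, 7 rose and 8 rose adjusted over the list alone (median 0.50, camera adjusted p = 0.00014, adjusted p = 0.352 with an estimated correlation). PIP2;7 (AT4G35100) rose by 1.22 (SE 0.20), TIP1;2 (AT3G26520) by 0.67 (SE 0.09) and PIP1;3 (AT1G01620) by 0.59 (SE 0.11), with adjusted p = 0.00336, 0.00163 and 0.00714. The aquaporin medians were 0.51, 0.54 and 0.41 on slides 1, 2 and 4 and 0.49 with the slide block (adjusted p = 0.000148). Of 21 wax and cutin genes, 6 rose and 10 rose adjusted over the list alone (median 0.37, camera adjusted p = 0.00166, adjusted p = 0.452 with an estimated correlation). CER1 (AT1G02205) and CER3 (AT5G57800), which act together in alkane synthesis, rose by 2.27 (SE 0.32, adjusted p = 0.00167) and 1.18 (SE 0.24, adjusted p = 0.0106). KCS1 (AT1G01120), a fatty acid elongase, rose by 1.29 (adjusted p = 0.00201) and the wax regulator MYB94 (AT3G47600) by 0.44 (adjusted p = 0.00968). The medians were 0.57, 0.21 and 0.26 on slides 1, 2 and 4 and 0.42 with the slide block (adjusted p = 0.000346). Of 13 vascular markers, 10 rose and 11 rose adjusted over the list alone (median 0.71, camera adjusted p = 8.9e-06, adjusted p = 0.402 with an estimated correlation). They included the phloem proton pump AHA3 (AT5G57350, 0.85, SE 0.12, adjusted p = 0.00206), the phloem regulator APL (AT1G79430, 0.52, SE 0.09, adjusted p = 0.00445), the secondary-wall cellulose synthase CESA7 (AT5G17420, 1.78, SE 0.31, adjusted p = 0.00478) and the sucrose exporter SWEET11 (AT3G48740, 0.50, SE 0.09, adjusted p = 0.00522). The medians were 1.02, 0.52 and 0.82 on slides 1, 2 and 4 and 0.67 with the slide block (adjusted p = 0.000114). Vascular markers thus rose beside the aquaporin and the wax and cutin lists.

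The ABA-related lists did not pass as lists in 1x salt. Of 24 ABA-responsive genes, 7 rose and 1 fell (median 0.20, camera adjusted p = 0.0615). The dehydrin gene RAB18 (AT5G66400) rose by 1.37 (SE 0.14, adjusted p = 0.00037) and LEA14 (AT1G01470) by 0.88 (SE 0.13, adjusted p = 0.00189), while HB12 fell. RD29B (AT5G52300), an ABA-induced marker, was 1.07 higher (SE 0.40, adjusted p = 0.0943), and its adjusted p was 0.0487 without no-salt array 1. The ABA-responsive list itself passed without 1x salt array 1 (median 0.34, adjusted p = 0.00486), without 1x salt array 3 (0.0331) and without no-salt array 2 (0.0499). Of 9 measured ABA receptors, 3 rose and 1 fell (median 0.32, adjusted p = 0.447). PYL5 (AT5G05440) rose by 2.73 (SE 0.47, adjusted p = 0.00454) and PYL9 (AT1G01360) fell by 0.87 (SE 0.15, adjusted p = 0.00489). Of 9 clade A PP2C phosphatases, which act against ABA signalling, 2 rose and 1 fell (median 0.06, adjusted p = 0.818), with HAI1 (AT5G59220) up by 1.32 (adjusted p = 0.00667) and HAB2 (AT1G17550) at -0.47 (adjusted p = 0.00763). Of 8 ABA kinases and ABF factors, ABF1 (AT1G49720) alone fell, by 0.38 (adjusted p = 0.00598; list median -0.13, adjusted p = 0.17). In ABA synthesis and breakdown, 1 of 13 genes rose and 2 fell (median -0.26, adjusted p = 0.352): NCED3 (AT3G14440), the rate-limiting step of ABA synthesis, fell by 0.98 (SE 0.25, adjusted p = 0.0243) and CYP707A4 (AT3G19270), which breaks ABA down, by 0.71 (SE 0.13, adjusted p = 0.00708). The NCED3 call was lost without no-salt array 2, 3 or 4 or 1x salt array 2 or 3 (0.0558 to 0.0749).

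Of 24 guard cell ion channels and pumps, 6 rose and 3 fell in 1x salt (median 0.11, adjusted p = 0.531). SLAH2 (AT4G27970), a nitrate-selective anion channel above background on 1 of 4 no-salt arrays, rose by 1.98 (SE 0.26, adjusted p = 0.00137) and the hexose transporter STP1 (AT1G11260) by 1.41 (SE 0.19, adjusted p = 0.0014). GORK (AT5G37500), the outward potassium channel of guard cells, rose by 0.67 (SE 0.19, adjusted p = 0.0366), a call lost without any 1 of the 4 no-salt arrays or without 1x salt array 2 or 3 (0.0545 to 0.122). The anion channel SLAC1 (AT1G12480) and the inward potassium channel KAT1 (AT5G46240) did not pass (0.19, SE 0.17, adjusted p = 0.492, and 0.18, SE 0.12, adjusted p = 0.381). Of 19 sodium, potassium and chloride genes, 4 fell and none rose (median -0.14, adjusted p = 0.0639, and 0.0398 without 1x salt array 3). CLC-G (AT5G33280) and the calcium sensor CBL10 (AT4G33000) fell by 0.39 and 0.38 (adjusted p = 0.0102 and 0.0153), the latter not without 1x salt array 3 (0.0617). The sodium transporter genes HKT1 (AT4G10310), NHX1 (AT5G27150) and SOS1 (AT2G01980) did not pass (0.73, SE 0.57, -0.23, SE 0.07, and -0.14, SE 0.08, adjusted p = 0.427, 0.0519 and 0.269). HKT1 was above background on 2 of 3 1x salt and 1 of 4 no-salt arrays, and NHX1 passed without 3x salt array 2 or 3 (0.0459 and 0.0415). In compatible solute synthesis, 3 of 12 genes rose and 2 fell (median -0.36, adjusted p = 0.549). P5CS1 (AT2G39800) and P5CR (AT5G14800), which make proline from glutamate, rose by 0.71 and 0.66 (adjusted p = 0.0052 and 0.00269), and MIPS2 (AT2G22240), an inositol phosphate synthase, fell by 0.90 (adjusted p = 0.00255). Of the 3 proline breakdown genes, PRODH1 (AT3G30775) rose by 1.74 (SE 0.29, adjusted p = 0.00379) and P5CDH (AT5G62530) by 0.46 (adjusted p = 0.0151, and 0.0627 without 1x salt array 3), with a list median of 0.46 (adjusted p = 0.126, and 0.0406 without 1x salt array 1). P5CS1 and P5CDH each had 1 of 2 probes of the opposite sign, and the mean of their probes gave no call. P5CDH then stood at -0.33 (adjusted p = 0.225), and in the authors' deposited table it passed in the opposite direction (-1.06, adjusted p = 0.0299).

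Among the other lists in 1x salt, 0 of 22 photosynthesis genes passed with limma, against 2 at an unadjusted p under 0.05 (median 0.08, camera adjusted p = 0.558, and a median of 0.15 with adjusted p = 0.0192 without 1x salt array 3). In the antioxidant list 1 of 10 rose and 2 fell (median -0.10, adjusted p = 0.67): the NADPH oxidase genes RBOHF (AT1G64060) and RBOHD (AT5G47910) moved by 0.64 and -1.11 (adjusted p = 0.00211 and 0.00733). Of 13 heat shock genes, HSP21 (AT4G27670), a chloroplast small heat shock protein above background on 1 of 3 1x salt arrays and no no-salt array, was at least 2.69-fold higher (adjusted p = 0.0248), but stood at -0.35 with normexp (adjusted p = 0.811). HSFA3 (AT5G03720) fell by 0.85 (adjusted p = 0.0358). The HSP21 call was lost without no-salt array 4 or 1x salt array 2 or 3 (0.0584 to 0.0792) and the HSFA3 call without no-salt array 2, 3 or 4 or 1x salt array 2 or 3 (0.078 to 0.127), while the heat shock list (median 0.39, adjusted p = 0.511) passed without 1x salt array 1 (median 1.13, 0.00827). Of 14 senescence genes, 3 rose and 6 fell (median -0.09, mean 0.24, camera direction down, adjusted p = 0.818), with the sugar transporter SAG29 (AT5G13170, above background on 1 of 4 no-salt arrays) up by 2.07 and the asparagine synthetase ASN1 (AT3G47340) by 2.66 (adjusted p = 1.69e-05 and 0.000247). Of 14 guard cell identity genes, the myrosinase TGG1 (AT5G26000) alone passed, up by 0.56 (adjusted p = 0.0161, and 0.0658 without 1x salt array 3; list median 0.05, adjusted p = 0.818). Of 7 pavement cell and trichome markers, 3 rose (median 0.29, adjusted p = 0.412), among them FDH (AT2G26250) by 0.64 and PDF1 (AT2G42840) by 1.16 (adjusted p = 0.00141 and 0.0105). XTH4 (AT2G06850) and XTH9 (AT4G03210) were the 2 of 12 wall-loosening genes that rose, by 2.93 and 2.55 (adjusted p = 0.00141 and 0.00528; list median 0.20, adjusted p = 0.447). Of 11 clock genes, 2 rose and 1 fell (median -0.03, mean 0.08, camera direction down, adjusted p = 0.896). ELF4 (AT2G40080) rose by 1.07 (adjusted p = 0.0122, and 0.0529 without 1x salt array 3) and LUX (AT3G46640) by 1.39 (adjusted p = 0.0237, lost without no-salt array 1, 3 or 4 or 1x salt array 2 or 3, 0.0508 to 0.0938). Adjusted over the list alone, the counts of genes up and down were 7 and 4 for ion channels, 4 and 1 for ABA receptors, 0 and 3 for ABA kinases, 1 and 3 for ABA synthesis, 0 and 5 for sodium genes, 3 and 3 for solute synthesis, 4 and 6 for senescence, 3 and 2 for pavement markers and 2 and 3 for clock genes, and the same as above for the rest.

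Over all genes tested, 2112 rose and 1843 fell in 1x salt (16.9%), and 681 and 547 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 7356 genes. All arrays of a group lay beyond those of the other for 29.6% of genes, where chance gives 5.71% if every array is independent. If close arrays are not independent, chance gives more, so this share does not exclude chance. Of the 68 genes that the naming rule took for this comparison and that passed, JAZ8, JAZ5, AOS and HSFA3 had overlapping arrays. With normexp background correction 475 rose and 612 fell, HSP21 changed sign, and the calls of CWINV5, XTH33, AT5G05965, AT4G15660, ERF14, SEP1, ABF1, CYP707A4, NCED3, SLAH2, CLC-G, CBL10, P5CDH, MYB94, JAZ8, JAZ5, JAZ1, AOS, HSFA3, SAG29, CESA7, PDF1, LUX and GORK were lost (adjusted p from 0.067 to 0.874). With slide as a block 551 genes rose and 430 fell, and 28 of the 68 named calls were lost (adjusted p from 0.05 to 0.175), those of PYL9, ABF1, CYP707A4, CLC-G, CBL10, PRODH1, P5CDH, KCS1, MYB94, CER3, RBOHD, JAZ8, JAZ5, JAZ1, AOS, CBP60G, HSP21, HSFA3, TGG1, AHA3, APL, CESA7, SWEET11, PDF1, PIP2;7, LUX, GORK and P5CS1. Leaving out no-salt array 3, 1x salt array 2 or 1x salt array 3 gave 1337, 1406 and 1204 genes up and 1172, 1133 and 1076 down, and 1207 and 1228 fell without no-salt array 2 or 4. Without 1x salt array 1, 5529 genes passed, 3455 of them among those called with all arrays. With close arrays averaged, which left 2 samples per group, limma called 2 genes up and 0 down, against 2037 and 1391 at an unadjusted p under 0.05, and none of the 68 named calls passed, although all 68 kept their direction and all 6 lists still passed camera. The 2 genes, chosen after their values were seen, were LEA18 (AT2G35300), of the late embryogenesis abundant proteins, and the xyloglucan transglucosylase XTH25 (AT5G57550), up by 4.06 and 3.67 (SE 0.17 each, adjusted p = 0.044).

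The comparison of 3x salt with no salt asked which genes differ after stepwise salt over the whole experiment. Of 24 ABA-responsive genes, 15 rose and 2 fell, with RAB18 4.74-fold and RD29B 5.89-fold higher. Of the jasmonate, salicylate, touch and wound, and photosynthesis lists, 16 of 20, 12 of 12, 13 of 14 and 20 of 22 genes fell. These lists passed camera at a preset correlation, with adjusted p from 0.352 to 0.463 with an estimated correlation. RAB18 rose by 2.25 on the log2 scale (SE 0.13, limma adjusted p = 3.43e-06), CA1 (AT3G01500), a carbonic anhydrase, fell by 2.32 (SE 0.23, adjusted p = 5.01e-05), and the jasmonate-marker defensin gene PDF1.2 (AT5G44420) was at least 62.2-fold lower (adjusted p = 7.08e-05).

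The largest rises in 3x salt included genes of late embryogenesis abundant (LEA) proteins, which accumulate in drying seeds and tissues. CWINV5 was at least 339-fold higher (adjusted p = 1.07e-05). LEA7 (AT1G52690) rose by 8.07 (SE 0.99, adjusted p = 0.000145), AT3G17520 by 6.78 (SE 0.48, adjusted p = 9.65e-06) and AT2G42560 by 8.22 (SE 1.31, adjusted p = 0.000611), the last above background on 1 of 4 no-salt arrays. AT5G66780 and the gibberellin-regulated GASA3 (AT4G09600) were not well above background in no salt and were at least 145-fold and 129-fold higher (adjusted p = 6.59e-05 and 8.91e-06). Among the largest falls, ARD3 fell by 5.56 (SE 0.57, adjusted p = 5.21e-05) and was above background on 1 of 4 3x salt arrays. PDF1.2, PDF1.2b (AT2G26020), ATHB54, AT2G27420 and AT1G70270 were not well above background in 3x salt. PDF1.2b was at least 24.9-fold lower, ATHB54 (AT1G27045), a homeobox factor, 28.1-fold, AT2G27420 23.7-fold and AT1G70270 22.9-fold (adjusted p = 4.81e-05, 9.54e-06, 0.000227 and 0.000133).

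Of 24 ABA-responsive genes, 15 rose and 2 fell by either adjustment (median 0.82, camera adjusted p = 0.00326, adjusted p = 0.452 with an estimated correlation). LTI30 (AT3G50970), a dehydrin gene, and the homeobox gene HB7 (AT2G46680) rose by 1.92 (SE 0.13, adjusted p = 6.64e-06) and 1.33 (SE 0.09, adjusted p = 8.91e-06), and RD29B by 2.56 (SE 0.37, adjusted p = 0.000343). The cold-regulated genes COR15B (AT2G42530) and KIN2 fell, COR15B by 1.04 (SE 0.09, adjusted p = 1.95e-05). On slides 1 and 6, the slides that hold both groups, the median was 1.15 and 0.76, and it was 0.93 with the slide block (adjusted p = 0.00297). Of 9 clade A PP2C genes, 6 rose and none fell, but the list did not pass (median 0.81, adjusted p = 0.0779, and 0.0441 without 1x salt array 1). HAI1 rose by 2.53 (SE 0.23, adjusted p = 2.96e-05), and AHG1 (AT5G51760), not well above background in no salt, was at least 12.6-fold higher (adjusted p = 0.000294). Of 9 ABA receptors, 2 rose and 3 fell (median -0.11, mean 0.09, camera direction down, adjusted p = 0.702), and PYL9 and PYL2 (AT2G26040) fell by 0.99 and 1.33 (adjusted p = 0.000307 and 0.00156). Of 8 ABA kinases and ABF factors, 2 rose and 1 fell (median -0.04, mean 0.03, camera direction up, adjusted p = 0.883). The seed ABA factor ABI5 (AT2G36270) rose by 0.91 (adjusted p = 0.000318) and ABF3 (AT4G34000) fell by 0.88 (adjusted p = 0.000223). Of 13 ABA synthesis and breakdown genes, 2 rose and 5 fell (median -0.20, adjusted p = 0.544). The ABA aldehyde oxidase AAO3 (AT2G27150) rose by 0.74 (adjusted p = 0.000227, and 0.865 with the mean of its probes), CYP707A3 (AT5G45340), which breaks ABA down, fell by 2.04 (SE 0.46, adjusted p = 0.00468), and NCED3 fell by 0.65 (SE 0.23, adjusted p = 0.0363). The NCED3 call was lost without no-salt array 2, 3 or 4 or 3x salt array 1 or 2 (0.067 to 0.0985), and PYL2 and CYP707A3 lost theirs with the slide block (0.0659 and 0.103).

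Of 20 jasmonate genes, 16 fell in 3x salt and 19 fell adjusted over the list alone (median -1.59, camera adjusted p = 6.7e-07, adjusted p = 0.402 with an estimated correlation). JAZ8, JAZ9 (AT1G70700) and AOS fell by 2.73, 1.21 and 1.62 (SE 0.27, 0.10 and 0.19, adjusted p = 4.26e-05, 1.78e-05 and 0.000108). The medians were -1.55 and -1.28 on slides 1 and 6 and -1.43 with the slide block (adjusted p = 1.83e-05). All 12 salicylate genes fell (median -1.23, camera adjusted p = 6.39e-05, adjusted p = 0.352 with an estimated correlation), with 12 also adjusted over the list alone. PAD4 fell by 2.15, the salicylate exporter gene EDS5 (AT4G39030) by 1.11, PR5 by 1.52 and SARD1 (AT1G73805) by 1.74 (adjusted p = 3.05e-05, 3.15e-05, 0.000187 and 0.00234). The medians were -1.46 and -1.27 on slides 1 and 6 and -1.31 with the slide block (adjusted p = 0.000225). Of 14 touch and wound genes, 13 fell and 14 fell adjusted over the list alone (median -1.81, camera adjusted p = 1.19e-06, adjusted p = 0.402 with an estimated correlation). CBF1, CBF2, WRKY40 and ERF5 (AT5G47230) fell by 1.88, 2.05, 2.86 and 3.13 (adjusted p = 2e-06, 8.54e-05, 6.43e-05 and 9.24e-05). The medians were -1.38 and -1.85 on slides 1 and 6 and -1.86 with the slide block (adjusted p = 1.83e-05).

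Of 22 photosynthesis genes, 20 fell and 22 fell adjusted over the list alone (median -0.79, camera adjusted p = 4.41e-07, adjusted p = 0.463 with an estimated correlation). The small Rubisco subunit genes RBCS2B (AT5G38420) and RBCS3B (AT5G38410) fell by 1.06 and 0.91, and the light-harvesting gene LHCA2 (AT3G61470) by 0.93 (SE 0.15, 0.14 and 0.14, adjusted p = 0.000309, 0.000507 and 0.000389). The medians were -0.97 and -0.73 on slides 1 and 6 and -0.89 with the slide block (adjusted p = 1.23e-08). These genes are abundant in mesophyll, and all 22 were also above background on every no-salt array of these guard-cell-enriched samples. Of 14 genes of guard cell identity and light signalling, 7 fell by either adjustment (median -0.31, camera adjusted p = 0.0326, adjusted p = 0.521 with an estimated correlation). The guard cell factor MYB60 (AT1G08810), the kinase gene CBC1 (AT3G01490), the blue-light receptor gene PHOT1 (AT3G45780) and RHC1 (AT4G22790), a transporter in the CO2 response, fell by 1.33, 0.76, 0.37 and 0.96 (adjusted p = 0.000256, 0.000574, 0.000793 and 0.000184). The medians were -0.06 and -0.62 on slides 1 and 6 and -0.48 with the slide block, where the call was lost (adjusted p = 0.0902), as it was without no-salt array 4 (0.0522), with normexp (0.102) and with the mean of a gene's probes (0.0507). Of 17 aquaporins, 8 fell and PIP2;5 rose, and 8 fell and 3 rose adjusted over the list alone (median -0.53, camera adjusted p = 0.0421, adjusted p = 0.463 with an estimated correlation). TIP1;2, TIP2;2 (AT4G17340), PIP2;1 (AT3G53420) and PIP2;8 (AT2G16850) fell by 0.57, 1.26, 0.72 and 1.19 (adjusted p = 0.00044, 0.00116, 0.000692 and 0.000599). The medians were -0.56 and -0.51 on slides 1 and 6, and the call was lost with the slide block (-0.40, adjusted p = 0.055) and without no-salt array 4, 3x salt array 3 or 3x salt array 4 (0.0551, 0.0689 and 0.077), and with normexp or quantile normalisation (0.141 and 0.0877).

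Of 24 ion channels and pumps, 6 rose and 8 fell in 3x salt (median 0.02, mean 0.19, camera direction down, adjusted p = 0.702). SLAH2, above background on 1 of 4 no-salt arrays, rose by 4.1 (SE 0.24, adjusted p = 3.87e-06) and GORK by 1.40 (SE 0.17, adjusted p = 0.000156). KAT1 fell by 0.94 (SE 0.12, adjusted p = 0.00015) and the nitrate transporter gene NRT1.1 (AT1G12110) by 1.11 (SE 0.09, adjusted p = 1.47e-05), while SLAC1 did not pass (-0.19, SE 0.15, adjusted p = 0.324). Of 19 sodium, potassium and chloride genes, 3 rose and 7 fell (median -0.03, adjusted p = 0.357), and CBL10 and CLC-G fell by 1.45 and 0.72 (adjusted p = 2.97e-06 and 5.36e-05). NHX1 and SOS1 did not pass (0.03 and -0.03, SE 0.07 each, adjusted p = 0.695 and 0.776). Nor did HKT1, above background on no 3x salt array and 1 of 4 no-salt arrays, which was at least 1.13-fold brighter in no salt (adjusted p = 0.321). In compatible solute synthesis 3 of 12 rose and 5 fell (median -0.78, adjusted p = 0.447), with 6 falling adjusted over the list alone. P5CR and P5CS1 rose by 1.26 and 0.94 (adjusted p = 1.21e-05 and 0.000152) and MIPS2 fell by 1.80 (adjusted p = 9.39e-06). Of the 3 proline breakdown genes, PRODH1 rose by 1.5 (adjusted p = 0.00115) and P5CDH by 0.59 (adjusted p = 0.000716, 1 of 2 probes of the opposite sign), and PRODH2 fell (median 0.59, adjusted p = 0.518). The direction of P5CDH turned with the mean of its probes (-0.11, adjusted p = 0.607) and in the authors' deposited table (-0.62, adjusted p = 0.076).

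Of 13 heat shock genes, 6 rose and 2 fell in 3x salt (median 1.31, adjusted p = 0.385). HSP21 was at least 36.8-fold higher (adjusted p = 7.65e-06) and the cytosolic chaperone gene HSP70-4 (AT3G12580) rose by 2.28 (SE 0.19, adjusted p = 2.13e-05). Of 14 senescence genes, 5 rose and 4 fell (median 0.04, adjusted p = 0.639), with SAG29, above background on 1 of 4 no-salt arrays, up by 5.35 (SE 0.11, adjusted p = 8.01e-09) and SAG21 (AT4G02380) by 1.88 (adjusted p = 4.81e-05). Of 21 wax and cutin genes, 8 rose and 7 fell (median -0.01, adjusted p = 0.67): CER1 rose by 3.00 (SE 0.29, adjusted p = 4.24e-05) and the cutin acyltransferase gene GPAT8 (AT4G00400) fell by 1.57 (SE 0.14, adjusted p = 3.13e-05). In the antioxidant list 2 of 10 rose and 3 fell (median -0.23, adjusted p = 0.352), with RBOHF up by 0.67 (adjusted p = 0.000202), and the iron superoxide dismutase gene FSD1 (AT4G25100) fell by 1.06 (adjusted p = 0.000144). Of 13 vascular markers, 2 rose and 4 fell (median 0.00, mean -0.06, camera direction down, adjusted p = 0.702). AHA3 rose by 0.63 (adjusted p = 0.00124) and XCP1 (AT4G35350), a xylem cysteine peptidase, fell by 1.53 (adjusted p = 0.000794). Of 7 pavement cell and trichome markers, 1 rose and 4 fell (median -0.49, adjusted p = 0.329), where FDH rose by 0.67 (adjusted p = 0.000119) and the epidermal factor gene PDF2 (AT4G04890) fell by 0.67 (adjusted p = 0.000395). Of 12 expansin and XTH genes, 1 rose and 6 fell (median -0.39, adjusted p = 0.388), with EXPA3 (AT2G37640) and EXPA4 (AT2G39700, above background on 2 of 4 3x salt arrays) at -2.40 and -1.98 (adjusted p = 0.000448 and 0.00033). Of 11 clock genes, 5 rose and 4 fell (median -0.03, mean 0.27, camera direction up, adjusted p = 0.849), and ELF4 and LUX rose by 2.05 and 1.76 (adjusted p = 5.85e-05 and 0.00142). Adjusted over the list alone, the counts of the lists that did not pass were unchanged except in solute synthesis.

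Over all genes tested, 6549 rose and 5515 fell in 3x salt (51.4%), 1244 and 1796 of them at least 2-fold. There were 13442 genes at an unadjusted p under 0.05. The arrays of the groups did not overlap for 51.7% of genes, where chance gives 2.86% if every array is independent, and more if close arrays are not. Of the 76 named genes that passed here, NCED3 had overlapping arrays. With normexp background correction 2987 rose and 3637 fell, and the calls of AHG1, HSP21, PHOT1 and NCED3 were lost (adjusted p = 0.898, 0.181, 0.103 and 0.0603). With slide as a block 4248 rose and 3767 fell. With close arrays averaged, 1145 rose and 1091 fell, 50 of the 76 named calls still passed, the guard cell identity and aquaporin lists did not (0.0666 and 0.0575), and 2227 of these 2236 genes were called in the same direction with all arrays counted singly.

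**Figure D2:**
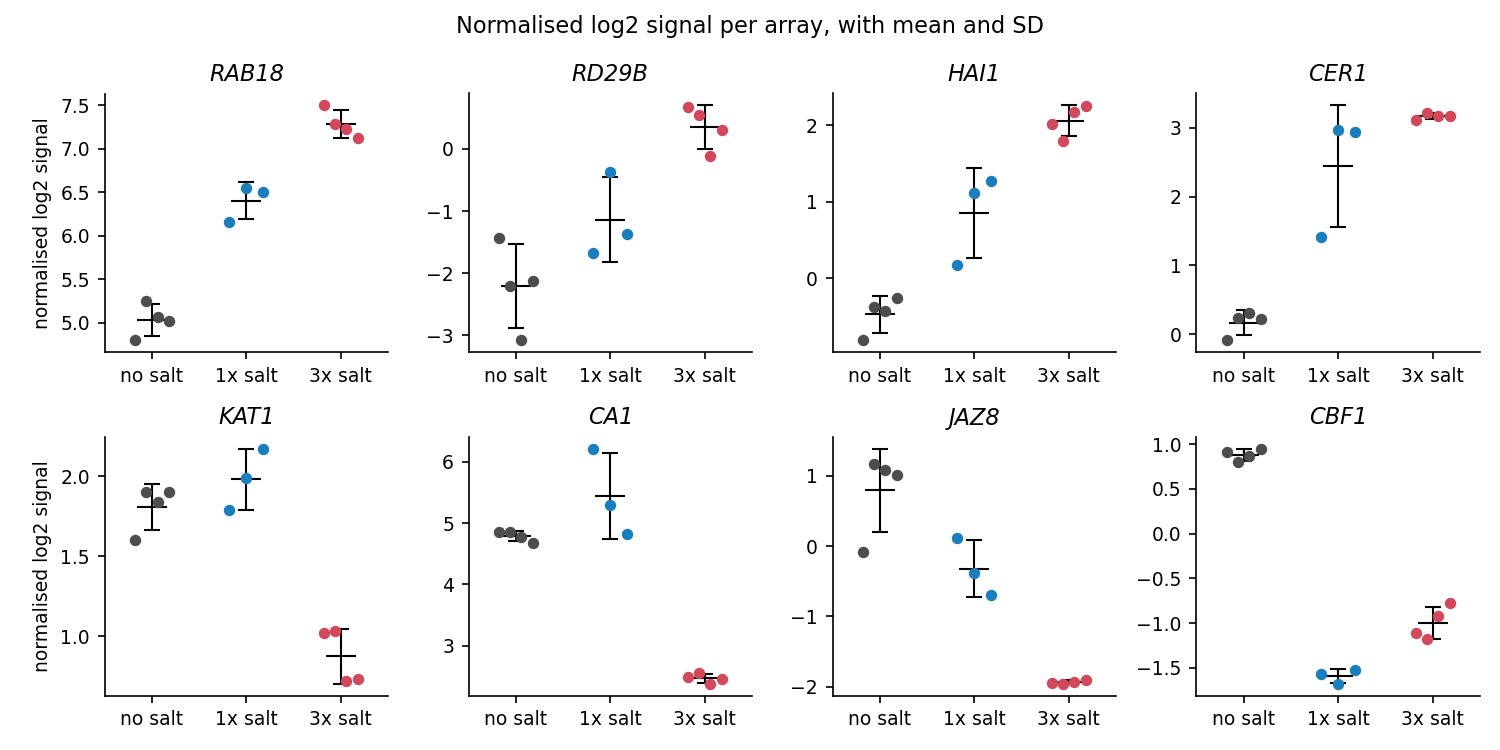
Normalised log2 signal (y axis) of RAB18, RD29B, HAI1, CER1, KAT1, CA1, JAZ8 and CBF1 on each array of the no-salt, 1x salt and 3x salt groups (dots), with the group mean (horizontal line) and SD (bars). Each y axis has its own range, and the log2 difference of 3x salt from no salt runs from -2.73 for JAZ8 to 3.00 for CER1.

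The comparison of 3x with 1x salt asked what earlier salt rounds add, since both groups received the last round. Of 24 ABA-responsive genes, 13 rose and 2 fell from 1x to 3x salt, and of 9 clade A PP2C phosphatases 6 rose. Genes that fell included 21 of 22 photosynthesis genes, 14 of 17 aquaporins, 10 of 13 vascular markers, 11 of 20 jasmonate genes, 8 of 14 guard cell identity genes and 8 of 21 wax and cutin genes. These lists passed camera at a preset correlation, with adjusted p from 0.317 to 0.463 with an estimated correlation. CA1 was 7.82-fold lower (log2 difference -2.97, SE 0.25, limma adjusted p = 6.79e-05) and HB7 2.40-fold higher (1.26, SE 0.10, adjusted p = 4.75e-05).

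The largest rises over 1x salt were those of bZIP5 (AT3G49760, 4.73, SE 0.24, adjusted p = 5.53e-06) and the LEA gene M17 (AT2G41260, 4.62, SE 0.48, adjusted p = 0.000167). HSP21 and AT1G20150 rose by 3.77 and 3.74 (SE 0.38 and 0.42, adjusted p = 0.000147 and 0.000211), AT5G66780 by 4.26 (SE 0.82, adjusted p = 0.003) and AT2G42560 by 4.41 (SE 1.41, adjusted p = 0.0318). The AT2G42560 call was lost without 3x salt array 3 or 4 (0.0662 and 0.0708). Of the 3 1x salt arrays, bZIP5, HSP21 and AT1G20150 were above background on 1, and M17, AT2G42560 and AT5G66780 on 2. AT3G16670 fell by 7.62 (SE 0.79, adjusted p = 0.000163) and was above background on 3 of 4 3x salt arrays. AT3G05730 and AT1G04800 fell by 5.92 and 4.75 (SE 0.45 and 0.41, adjusted p = 4.44e-05 and 7.59e-05). The thionin gene THI2.2 (AT5G36910), the protease gene SDD1 (AT1G04110), which limits stomatal density, and AT1G13650 were not well above background in 3x salt. They were at least 45.5-fold, 18.8-fold and 17.5-fold lower (adjusted p = 2.14e-05, 1.01e-05 and 0.00061).

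Of 24 ABA-responsive genes, 13 rose and 2 fell by either adjustment (median 0.74, camera adjusted p = 0.0185, adjusted p = 0.463 with an estimated correlation). LTI30 and HB12 (AT3G61890) rose by 1.08 and 1.15, RD29B by 1.49, and COR15B fell by 0.82 (adjusted p = 0.000358, 0.000482, 0.0147 and 0.000217). RD29B did not pass without 1x salt array 1 (0.0587). With the slide block the median was 0.95 (adjusted p = 0.00527), and the list did not pass with array weights (0.0654). Slide 1 alone holds both groups and gave 1.13, but slide 1 values here rest on 1x salt array 1, which lay apart. Of 9 clade A PP2C genes, 6 rose and 7 rose adjusted over the list alone (median 0.84, camera adjusted p = 0.0205, adjusted p = 0.452 with an estimated correlation). HAI1, HAI2 (AT1G07430), HAB1 (AT1G72770) and ABI2 (AT5G57050) rose by 1.21, 0.95, 0.84 and 0.65 (adjusted p = 0.00388, 0.00643, 0.00209 and 0.00592). The median was 1.19 on slide 1 and 0.87 with the slide block (adjusted p = 0.00893), and the list did not pass when only genes above background on all arrays were kept (0.059).

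Of 22 photosynthesis genes, 21 fell and 22 fell adjusted over the list alone (median -0.86, camera adjusted p = 1.25e-08, adjusted p = 0.452 with an estimated correlation). RBCS2B, RBCS3B and RBCS1B (AT5G38430) fell by 1.35, 1.2 and 0.98 (adjusted p = 0.000284, 0.000355 and 0.000599). The median was -1.13 on slide 1 and -0.92 with the slide block (adjusted p = 4.33e-10). Of 20 jasmonate genes, 11 fell and 14 fell adjusted over the list alone (median -0.96, camera adjusted p = 1.12e-05, adjusted p = 0.452 with an estimated correlation), on slide 1 -1.18 and with the slide block -0.98 (adjusted p = 3.06e-05). JAZ9, JAZ8, JAZ2 (AT1G74950) and the jasmonate synthesis gene OPR3 (AT2G06050) fell by 0.92, 1.61, 1.01 and 0.97 (adjusted p = 0.000231, 0.00201, 0.00176 and 0.000888). Of 17 aquaporins, 14 fell by either adjustment (median -1.03, camera adjusted p = 5.34e-07, adjusted p = 0.317 with an estimated correlation), on slide 1 -0.96 and with the slide block -1.06 (adjusted p = 3.29e-06). TIP2;1, PIP2;8, TIP1;2 and PIP2;1 fell by 2.07, 1.69, 1.24 and 1.02 (adjusted p = 0.000199, 3e-04, 4.06e-05 and 0.00033). Of 21 wax and cutin genes, 8 fell by either adjustment (median -0.26, camera adjusted p = 0.00326, adjusted p = 0.452 with an estimated correlation), on slide 1 -0.32 and with the slide block -0.29 (adjusted p = 0.00913). GPAT8 and the fatty acid hydroxylase genes CYP86A4 (AT1G01600), CYP86A8 (AT2G45970) and CYP86A2 (AT4G00360), which act in cutin synthesis, fell by 2.03, 1.70, 1.46 and 0.92 (adjusted p = 4.23e-05, 0.000653, 0.000229 and 0.000654).

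Of 13 vascular markers, 10 fell and 11 fell adjusted over the list alone (median -0.68, camera adjusted p = 9.59e-05, adjusted p = 0.452 with an estimated correlation), on slide 1 -0.36 and with the slide block -0.70 (adjusted p = 0.00281). XCP1, XCP2 (AT1G20850), the sieve element gene SEOR1 (AT3G01680) and the phloem lectin gene PP2-A1 (AT4G19840) fell by 2.70, 1.53, 1.55 and 0.68 (adjusted p = 0.00015, 0.00214, 0.000201 and 0.00125). Of 14 guard cell identity genes, 8 fell by either adjustment (median -0.53, camera adjusted p = 0.00526, adjusted p = 0.463 with an estimated correlation), on slide 1 -0.40 and with the slide block -0.57 (adjusted p = 0.0343). MYB60, RHC1, TGG1 and TGG2 (AT5G25980) fell by 1.17, 0.81, 0.82 and 1.56 (adjusted p = 0.00148, 0.00129, 0.00104 and 0.00124). Of 7 pavement cell and trichome markers, 5 fell by either adjustment (median -0.43, camera adjusted p = 0.0228, adjusted p = 0.352 with an estimated correlation), on slide 1 -0.71 and with the slide block -0.56 (adjusted p = 0.0499). PDF1, ATML1 (AT4G21750), PDF2 and the trichome patterning gene TRY (AT5G53200) fell by 1.78, 0.43, 0.40 and 1.1 (adjusted p = 0.000491, 0.0148, 0.0149 and 0.0183). ATML1 did not pass without 1x salt array 1 or 2 (0.0515 and 0.0505) nor TRY without 1x salt array 1 (0.0714), and the list did not pass with quantile normalisation (0.0845) or the authors' table (0.0566). Of 12 expansin and XTH genes, 6 fell by either adjustment (median -0.84, camera adjusted p = 0.0207, adjusted p = 0.452 with an estimated correlation), on slide 1 -1.07 and with the slide block -0.99 (adjusted p = 0.0294). EXPA3, EXPA4, EXPA15 (AT2G03090) and XTH9 fell by 1.73, 1.22, 0.75 and 1.86 (adjusted p = 0.00653, 0.0108, 0.00292 and 0.00938), with EXPA4 above background on 2 of 4 3x salt arrays. Vascular and photosynthesis markers thus fell beside guard cell, aquaporin, jasmonate and wax lists.

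From 1x to 3x salt KAT1 and NRT1.1 fell by 1.11 and 0.95 (SE 0.12 and 0.09, adjusted p = 0.000219 and 0.000123), and GORK was higher by 0.73 (SE 0.19, adjusted p = 0.0126), while SLAC1 did not pass (-0.38, SE 0.17, adjusted p = 0.0982). In this ion channel list 6 of 24 rose and 8 fell (median -0.13, adjusted p = 0.421). Of 19 sodium genes, 3 rose and 3 fell (median 0.02, mean -0.06, camera direction down, adjusted p = 0.818). The calcium sensor gene SOS3 (AT5G24270) and NHX1 rose by 0.95 and 0.27, and CBL10 fell by 1.07 (adjusted p = 0.00142, 0.0154 and 4.79e-05). SOS1 (0.11, SE 0.08, adjusted p = 0.294) did not pass. Nor did HKT1, above background on 2 of 3 1x salt arrays and no 3x salt array, which was at least 1.87-fold brighter in 1x salt (adjusted p = 0.0793), and it passed without 3x salt array 1 (0.0184). Of 9 ABA receptors, 2 fell and 1 fell adjusted over the list alone (median -0.43, adjusted p = 0.127), PYL7 (AT4G01026) by 0.38 (adjusted p = 0.0152, and 0.0539 without 1x salt array 3). PYL2 fell by 0.75 (adjusted p = 0.0488), a call lost without any 1 of no-salt arrays 2, 3 and 4, 1x salt arrays 1 and 3 and the 4 3x salt arrays (0.0529 to 0.166). Of 8 ABA kinases and ABF factors, 3 rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone (median 0.25, adjusted p = 0.329), with ABF1 and ABI5 up by 0.54 and 0.92 (adjusted p = 0.000382 and 0.000854). Of 13 ABA synthesis and breakdown genes, 2 rose and 1 fell, and 1 and 1 adjusted over the list alone (median -0.01, mean -0.01, camera direction up, adjusted p = 0.818). ABA3 (AT1G16540) rose by 0.37 (adjusted p = 0.008), and ABA2 (AT1G52340) fell by 0.35 (adjusted p = 0.0246), not without 1x salt array 1 or 3 or 3x salt array 3 or 4 (0.0527 to 0.0852). NCED3 did not pass (0.33, SE 0.25, adjusted p = 0.328). In solute synthesis 2 of 12 rose and 2 fell (median -0.16, adjusted p = 0.818): P5CR rose by 0.60 and MIPS2 fell by 0.90 (adjusted p = 0.00147 and 0.000855), while P5CS1 did not pass (0.23, SE 0.12, adjusted p = 0.179). For proline breakdown, 0 of 3 genes passed with limma, against 1 at an unadjusted p under 0.05 (median -0.24, camera adjusted p = 0.724).

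Of 13 heat shock genes, 4 rose and 1 fell (median 0.02, adjusted p = 0.544), with HSP70-4 up by 2.03 (SE 0.21, adjusted p = 0.00015). Of 14 senescence genes, 6 rose and 3 fell (median 0.36, adjusted p = 0.329): SAG29 rose by 3.27 (SE 0.12, adjusted p = 1.11e-06) and ASN1 fell by 2.18 (SE 0.24, adjusted p = 0.000206). Of 12 salicylate genes, 2 rose and 2 fell, and 1 and 2 adjusted over the list alone (median -0.14, adjusted p = 0.702), with PBS3 up by 0.65, and EDS5 fell by 0.58 (adjusted p = 0.00824 and 0.00255). Of 14 touch and wound genes, CBF1 and CBF3 rose by 0.59 and 0.95 (adjusted p = 0.00168 and 0.0103) and TCH3 fell, though not adjusted over the list alone (median -0.03, adjusted p = 0.985). FSD1 alone of 10 antioxidant genes passed and fell by 1.17 (adjusted p = 0.000287; list median -0.09, adjusted p = 0.447). ELF4 alone of 11 clock genes passed and rose by 0.98 (adjusted p = 0.008; list median 0.03, adjusted p = 0.67).

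Over all genes tested, 4779 were higher and 4369 lower in 3x than in 1x salt (39%), 698 and 1516 of them at least 2-fold. Quantile normalisation moved this split to 6049 higher and 3577 lower. There were 11321 genes at an unadjusted p under 0.05. No overlap between the arrays was seen for 42.3% of genes, where chance gives 5.71% if every array is independent, and more if close arrays are not. Of the 76 named genes that passed here, PYL2 had overlapping arrays. With normexp background correction 1606 rose and 1928 fell, and 14 of these calls were lost (adjusted p from 0.0709 to 0.435), those of HSP21, AT1G20150, AT1G13650, PYL7, PYL2, ABA3, ABA2, PBS3, PDF2, TRY, EXPA15, EXPA4, CBF1 and NHX1. With slide as a block the counts were 1259 and 1581, and 28 of the 76 named calls were lost (adjusted p from 0.0526 to 0.314), those of AT2G42560, AT5G66780, COR15B, PYL7, PYL2, HAB1, ABI2, HAI2, ABA3, ABA2, SOS3, P5CR, JAZ8, TGG1, MYB60, PP2-A1, XCP2, PDF1, ATML1, PDF2, TRY, XTH9, EXPA4, CBF1, CBF3, GORK, NHX1 and RD29B. With close arrays averaged, 123 rose and 332 fell, 453 of these 455 in the same direction as with all arrays, and 17 of the 76 named calls passed. Without 1x salt array 1, 7554 genes passed, 6943 of them among those called with all arrays.

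**Figure D3:**
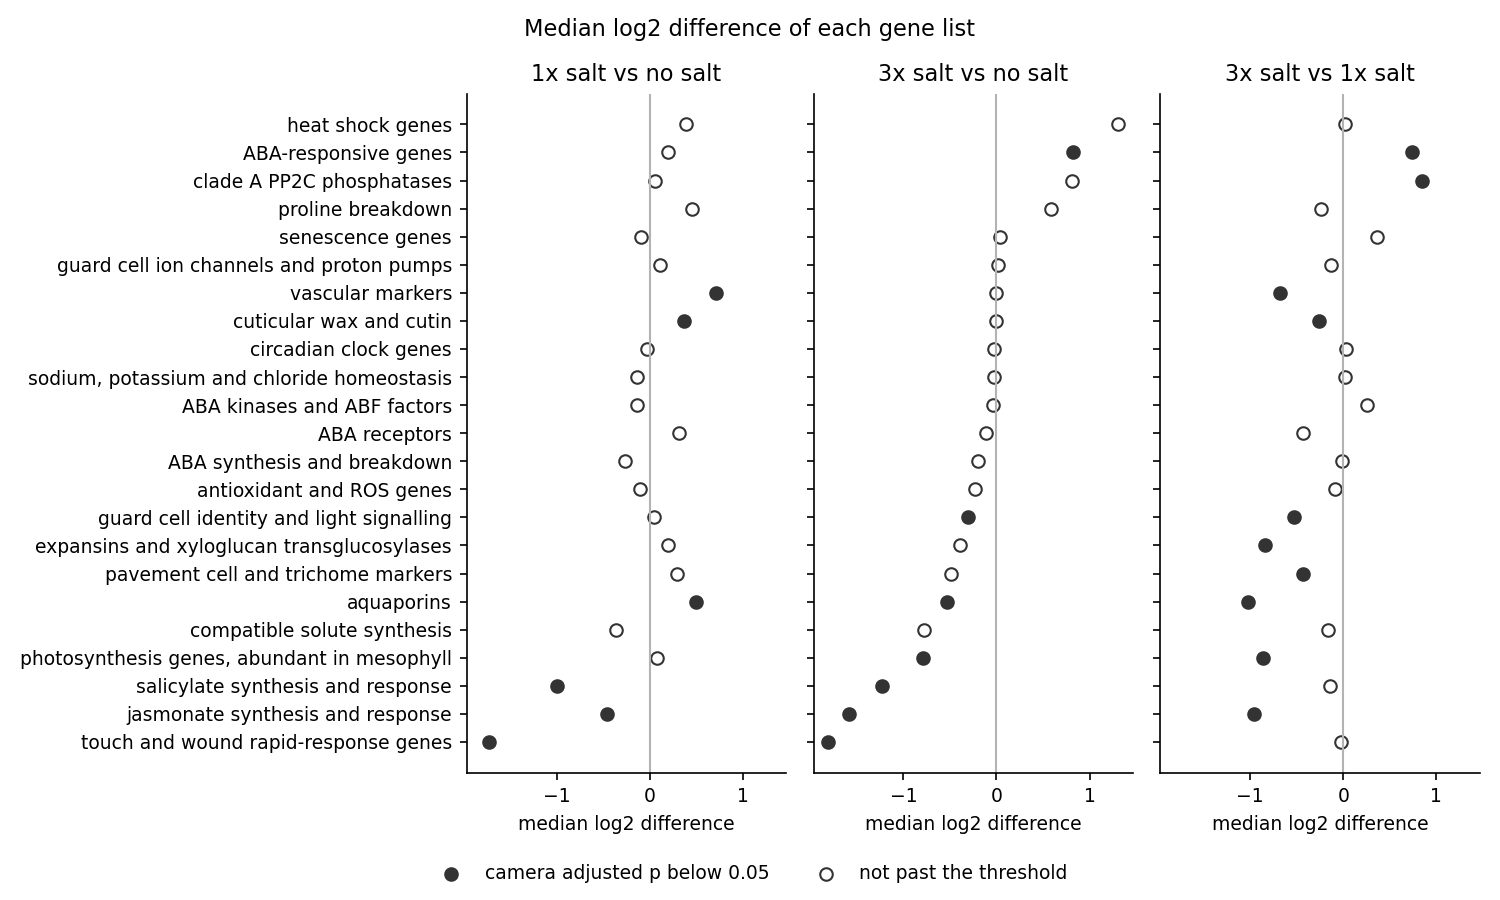
Median log2 difference (x axis) of the measured members of each of the 23 gene lists (y axis) for 1x salt against no salt, 3x salt against no salt and 3x against 1x salt. Filled dots mark lists with a camera adjusted p below 0.05 at a preset correlation, 6, 7 and 10 in the 3 comparisons, and none of these passes with an estimated correlation.

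Both salt comparisons use the same 4 no-salt arrays. Across genes, their log2 differences correlated with r = 0.559 and a covariance of 0.251. Unchanged groups sharing a no-salt group were drawn 100 times with replacement from residuals of all arrays. They gave a mean r of 0.437 (median 0.538, highest 0.947) and a mean covariance of 0.029 (median 0.024, highest 0.175). The observed covariance lay 0.222 above this mean. Genes are not independent replicates, so no p is given. In both comparisons 1143 genes rose and 1350 fell with limma, where independent lists this long would share 590 and 433. Unchanged groups share 0 by construction and are no test. Genes called in opposite directions numbered 286, against 1011 for independent lists, and 216 of these rose in 1x and fell in 3x salt. With the no-salt arrays split between the comparisons, in 6 ways, r was 0.468 to 0.528 and the covariance 0.223 to 0.242. Shared genes were 92 to 189 up, 46 to 252 down and 2 to 19 opposite, but fewer arrays let fewer genes pass. CER1, RAB18, SLAH2 and CWINV5 rose and FMO1, ARD3, JAZ8 and CBF1 fell in both. The count up in both was 754, 701, 713 and 654 without no-salt array 2 or 3 or 1x salt array 2 or 3, and 2037 without 1x salt array 1. The count down in both was 874, 833 and 805 without no-salt array 3 or 1x salt array 2 or 3, and the opposite count was 153, 137, 159 and 188 without no-salt array 2, 3 or 4 or 1x salt array 3. With slide as a block, 310 rose in both, 335 fell in both and 49 were opposite. With close arrays averaged, limma called LEA18 and XTH25 up in both (2 genes), 0 down in both and 0 opposite.

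**Figure D4:**
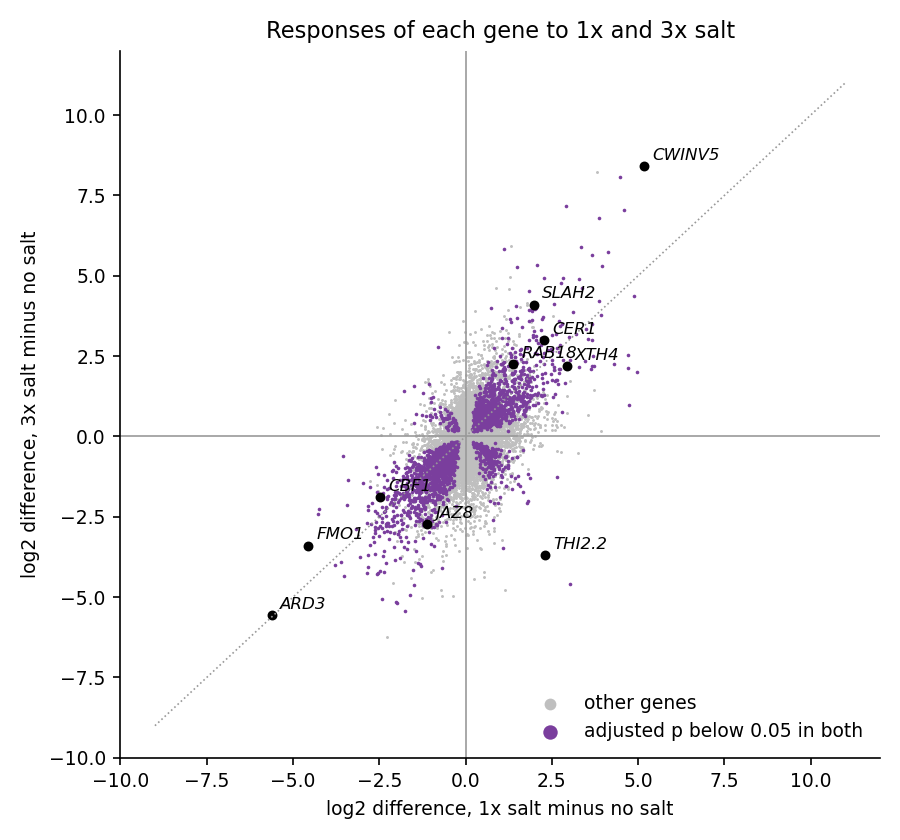
Log2 difference of each gene in 3x salt against no salt (y axis) plotted on that in 1x salt against no salt (x axis), with genes past an adjusted p of 0.05 in both comparisons in purple, named genes labelled in black and the line of equal change dotted. Of the genes past the threshold in both, 1143 lie up in both, 1350 down in both and 286 in opposite directions (r = 0.559 across all genes).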

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

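The tests of a wrong label, of the distance between slide 1 arrays, of a lower guard cell share and of brightness-matched lists were chosen after the result was seen.

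In groups of 4 arrays, 33 of 346 tested levels had an array far from the others, where chance flags about 1 in 20. The value is the gap to the nearest array over the whole range. No-salt array 1 stood apart for AT3G21460 (0.897), AT4G15660 (0.845), NAS1 (0.862), LEA14 (0.847), MYB94 (0.84), JAZ8 (0.872), JAZ5 (0.877), JAZ1 (0.947), PR5 (0.884), XTH9 (0.883), WRKY40 (0.861), CYP707A3 (0.973), OPR3 (0.86) and SEOR1 (0.84). It also stood apart for the mean level of the ion channel (0.841), photosynthesis (0.884), wax and cutin (0.881), jasmonate (0.9), salicylate (0.908), guard cell identity (0.866), vascular (0.935) and touch and wound lists (0.846). No-salt array 4 stood apart for AT3G05730 (0.984). Near background it did for CWINV5 (0.928), HSP21 (0.956), GASA3 (0.913), AHG1 (0.919), bZIP5 (0.864), M17 (0.881) and AT1G20150 (0.908), which may be noise. No-salt array 2 did for CYP707A4 (0.847), and 3x salt array 1 for AHA3 (0.881) and the ABA synthesis list (0.939).

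Some named genes moved one way in 1x and the other way in 3x salt. PDF1, TIP1;2, XCP1, AT3G16670, THI2.2 and SEOR1 rose in 1x and fell in 3x salt, with log2 differences between 3x and 1x salt of -1.78, -1.24, -2.70, -7.62, -6.00 and -1.55, and HB12 fell in 1x and rose in 3x salt (1.15). The value of THI2.2, not well above background in 3x salt, is a fitted one and no bound.

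Array 1 of 1x salt lay apart from arrays 2 and 3. A no-salt sample under its label would lie as close to a no-salt array as these lie to each other, but its smallest SD of log2 differences to one was 0.457, against at most 0.277. An effect of slide 1 would move the other arrays of that slide alike: its deviation correlated across genes with that of 3x salt array 1 at 0.28 and with that of no-salt array 1 at 0.09, and the slide 1 and slide 3 arrays of 3x salt differed by an SD of 0.157 against 0.433 here, so it is excluded as the whole difference. The same response at a smaller size would track that of arrays 2 and 3, but over splits of the no-salt arrays the correlation across genes was 0.43 to 0.48. A different response of those plants or a different preparation also stays open, and no group of the design tests it.

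Vascular markers were higher in 1x salt than in the other groups. A lower share of guard cells would raise the photosynthesis list as well, but the vascular list moved more by 0.75 (SE 0.17). This SE is across genes, not across samples. On 1x salt array 1 both lists stood above no salt, at 0.706 (vascular) and 0.515 (photosynthesis). On arrays 2 and 3 the vascular list stood at 0.90 and 0.96, and the photosynthesis list at -0.03 and -0.16. A lower guard cell share is thus not excluded for array 1. More vascular tissue in these samples may be the source: the lowest median of the phloem or xylem markers on a 1x salt array was 0.35, although the xylem markers also stood at 0.96 and 1.00 on 3x salt arrays 1 and 2 and at -0.22 and -0.24 on arrays 3 and 4. All 13 markers were above background on every no-salt array, none is in another list, and the labels name no sort or gate, with normalised log2 levels in no salt, 1x and 3x salt of 5.70, 6.01 and 5.33 for PP2-A1 and 4.46, 5.01 and 4.46 for SUC2. A change of these genes within guard cells by salt stays open as untested.

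Photosynthesis genes were lower in 3x salt. Brightness-matched other genes had a median of -0.31, between the limits set beforehand for and against compression or scaling of bright probes. The planned test thus left that cause undecided. In a later test, 0 of 10000 random lists matched on brightness had a median as low as -0.79 (lowest -0.72). The photosynthesis list fell further, but random lists do not move together as its genes do (estimated correlation 0.78). Compression or scaling is thus not excluded. Less mesophyll RNA stays undecided. Photorespiration genes (11 measured, CAT2 also in the antioxidant list), listed before the test though after the data were seen, had a median of -0.75. Less mesophyll would raise epidermal markers, but guard cell identity and pavement markers had medians of -0.31 and -0.49. Salt itself may move each list. LHCB1.3, PSBO1 and LHCB2.2 stood at 8.12, 7.91 and 7.88 in no salt and 7.65, 7.48 and 7.02 in 3x salt. All 22 genes were above background on every no-salt array and the labels name no sort or gate. A fall within guard cells stays open as untested.

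Taking every array as an independent sample, other splits of the arrays into groups of the same sizes excluded chance for the counts of genes: only the real split, 1 of 35, gave as many in each comparison (3955, 12064 and 9148 genes, against at most 171, 0 and 301 with limma). With close arrays averaged, which left 2, 2236 and 455 genes, a group has 2 samples and the splits are too few for a share under 0.05. For the number of lists, again with every array taken as independent, 1 of 35 splits, the real one, gave the 10 lists of 3x against 1x salt (highest other 9). This is a margin of 1 list, and quantile normalisation, the authors' table, array weights and the filter on all arrays also gave 9 with the real split. For none of these 10 lists taken alone is chance excluded: 2 of 35 splits gave as small a p for photosynthesis and aquaporins, 3 for pavement markers, and 5 to 11 for the others. In 1x and 3x salt against no salt, 10 and 6 of 35 splits gave as many as the 6 and 7 lists (highest other 8 and 9), so chance is not excluded for these counts. Only the real split gave as small a p for 1 of the 6 and 2 of the 7 lists.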

How the results depend on the processing

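Median centring and the averaging or blocking of close arrays were chosen after the result was seen. The rest was planned, normexp on the mean spot intensity. Of 6068 comparisons of a named gene with an alternative, 5638 kept direction and side of the threshold, 412 lost the call, 13 gained it and 5 changed sign. For lists the figures were 1746 of 1863, 40 and 77 with none reversed, and for counts of genes or lists 241 of 321 stayed within 1.5 times. Where no cause is given, the cause was not tested. With normexp, which moved the median of all genes from 0.029, 0.037 and 0.016 to -0.10, -0.16 and -0.058, there were 475 up and 612 down in 1x salt, 2987 and 3637 in 3x salt, 1606 and 1928 for 3x against 1x salt, 244 up in both, 514 down in both, 35 opposite and a correlation of 0.63, and HSP21 in 1x salt turned to -0.35 (adjusted p = 0.811). Without a filter on dim probes, 1224 fell in 1x salt, 728 rose in both, 140 were opposite and the correlation was 0.44, with more genes tested. With the mean of probes P5CDH turned to -0.33 and -0.11 (adjusted p = 0.225 and 0.607), since its 2 probes have opposite signs. With the authors' table it was -1.06 and -0.62 (adjusted p = 0.0299 and 0.076), 1305 genes rose in 1x salt, 698 rose in both and 185 were opposite. With slide as a fixed block, there were 551 and 430, 4248 up in 3x salt, 1259 and 1581, 310, 335 and 49, with fewer degrees of freedom. Array weights, 0.23 (1x salt array 1) to 2.92 (no-salt array 2), gave 4265 and 3621 in 1x salt, 2706 up in both, 2649 down in both and 626 opposite. At least 2-fold, there were 681 and 547, 1244 and 1796, and 698 and 1516. With close arrays averaged there were 2 and 0 by limma, 1145 and 1091, and 123 and 332, with 2 up in both, 0 down in both, 0 opposite and a correlation of 0.50; at an unadjusted p under 0.05 there were 2037 and 1391, 4541 and 3864, and 3617 and 3675. With close arrays as a random block (correlation 0.608) there were 720 and 578, 3852 and 3400, and 2684 and 2797, with 360, 429 and 42; lists were not run with random blocks. Camera with an estimated correlation passed 0, 0 and 0 lists, against 4, 1 and 2 at an unadjusted p under 0.05; fry passed 11, 16 and 15 lists in 1 direction, without jasmonate in 1x salt (adjusted p = 0.0732), and 19, 23 and 20 in either direction.

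Leaving out each array gave 1204 to 3008 up and 1076 to 2521 down in 1x salt, 5631 to 6905 and 4775 to 5874 in 3x salt, and 3866 to 4787 and 3688 to 4431 for 3x against 1x salt. Up in both ranged from 654 to 2037, down in both from 805 to 1987, opposite from 137 to 291 and the correlation from 0.48 to 0.62, which was 0.62 without 1x salt array 1 and 0.48 and 0.49 without array 2 or 3; lists ranged from 6 to 9, 5 to 8 and 10 to 10. The ABA-responsive list in 1x salt passed also with normexp (adjusted p = 0.000331), the authors' table (0.0282) and array weights (0.00869). In 1x salt the proline breakdown (0.0168) and photosynthesis lists (0.00562) passed with normexp and the sodium list without a filter (0.0141); the PP2C list in 3x salt passed with normexp, no filter, the authors' table and only 2 groups (0.0221, 0.0133, 0.0235 and 0.0461). Of 68, 76 and 76 named calls, 43, 72 and 62 held with normexp and 47, 74 and 69 with close arrays as a random block.

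The replicate numbers were not taken to pair the samples, since the labels give them no shared batch and not every same-numbered pair correlated above 0.1. Deviations of same-numbered arrays correlated at 0.09, 0.12 and 0.15 (no salt and 1x salt), 0.01, 0.07, 0.23 and 0.07 (no salt and 3x salt) and 0.27, -0.12 and 0.30 (1x and 3x salt), and the own number was highest in 16 of 20 cases, a hint of shared deviations from the data and not from the design. Each same-numbered pair of no-salt and 1x salt arrays also shares a slide. With the replicate block there were 1730 up and 1560 down, 6803 and 5819, and 4770 and 4400, and no list call changed. Signal over background limits dim genes: log2 differences of genes above background on only some arrays of a group rest in part on signals near background.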

Other observations

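The families were chosen after the data were seen, though before their own results, and their tests are to be read as hypotheses.

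Gene families outside the lists were taken by symbol, and chance is not excluded for the number that passed. In 1x salt 14 of 36 arabinogalactan protein genes rose and 4 fell (median log2 difference 0.74, camera adjusted p = 0.0065, adjusted p = 0.577 with an estimated correlation). Of the cell cycle cyclins 9 of 31 rose (0.34, adjusted p = 0.00614, 0.494 with an estimated correlation), and of the large ribosomal subunit 4 of 25 (0.22, adjusted p = 0.0065, 0.48 estimated). Members fell among glutamate receptor-like channels (5 of 13, -0.33), cysteine-rich receptor-like kinases (9 of 25, 2 rose, -0.51), U-box ligases (6 of 21, -0.20) and ERF and DREB factors (8 of 23, 3 rose, -0.22), with adjusted p from 0.00614 to 0.0151 and from 0.48 to 0.494 with an estimated correlation.

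In 3x salt against no salt, 6 families passed, each with more genes falling than rising. Those that fell were 9 of 13 SAUR auxin-response genes (1 rose, median -2.07, adjusted p = 0.00919), 18 of 28 cellulose synthase and related genes (4 rose, -0.82, adjusted p = 0.000332), 11 of 17 Aux/IAA repressors of auxin signalling (2 rose, -0.58, adjusted p = 0.00614) and 11 of 17 histones (2 rose, -0.45, adjusted p = 0.00694). Of cysteine-rich receptor-like kinases 14 of 25 fell and 3 rose (-0.52, adjusted p = 0.0251), and of U-box ligases 9 of 21 fell and 1 rose (-0.25, adjusted p = 0.0208), while cyclins (median -0.34, adjusted p = 0.0777) and arabinogalactan proteins (-0.32, adjusted p = 0.18) did not pass. Against 1x salt, members fell among arabinogalactan proteins (21 of 36, 4 rose, -1.13), cyclins (13 of 31, 1 rose, -0.47), cellulose synthases (18 of 28, 2 rose, -0.82), histones (12 of 17, -0.41), SAUR (8 of 13, 1 rose, -1.23), Aux/IAA (11 of 17, 2 rose, -0.56), trehalose phosphate synthases and phosphatases (6 of 19, -0.33) and peroxidases (5 of 12, -0.35) (adjusted p from 0.000183 to 0.0436). Members rose among glycosyltransferases of the UGT family (21 of 49, 3 fell, 0.44, adjusted p = 0.00364) and heat shock factors (6 of 14, 0.32, adjusted p = 0.0122). With an estimated correlation these adjusted p-values were 0.48 to 0.577.

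The hypothesis that families outside the lists move together was left undecided. Of 28 families, 7, 6 and 10 passed in 1x and 3x salt against no salt and in 3x against 1x salt, and 2, 7 and 8 of 35 splits of the arrays gave as many (highest other 7, 11 and 11), so chance is not excluded. All 23 calls kept their direction with normexp, quantile normalisation and median centring, and the cyclins in 1x salt no longer passed with normexp (adjusted p = 0.667).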
